A study of Homo sapiens with 6 samples.

How the data were processed

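RNA-seq was done on human umbilical vein endothelial cells carrying the FUCCI cell cycle reporter and sorted by flow cytometry into early G1 (3 libraries) and late G1 (3 libraries). The authors deposited 1 table of counts per gene symbol, with 1 column per library, and no normalization was applied to these values. Per the submitters' processing notes, reads were aligned to hg19 with STAR, whose version is not given in the sources used here. The counting tool, the annotation behind the counts, the strand setting and the gate colours of the sort are not given either. Values were checked to be whole numbers, with totals from 16021700 to 21752999 per library, and 99.9% of the counts fell in genes that were tested. A count of 3 in a library, taken as the upper limit behind a count of 0, was 0.138 to 0.187 CPM. PCR copies are not independent molecules, so this limit covers counting error only.

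Of 26475 symbols, 22606 matched the GENCODE annotation lifted to GRCh37 by current symbol and 1350 through an older symbol; coordinates are from that annotation. Genes with enough counts were taken with filterByExpr, libraries were scaled by TMM, and late G1 was compared with early G1 by the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 3.57%. Standard errors were obtained from the log2 fold change and the F statistic. CPM used TMM-scaled totals. GC content and length were available for 97.9% of the tested genes. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

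The 34 gene lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined. The 30 lists with at least 3 tested genes were tested with camera on voom values (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over those lists. The lists were also tested with an estimated correlation, which bases the test on fewer degrees of freedom and so tends to give larger p-values. They were tested with fry too, which asks whether a list's genes move one way on balance and does not compare them with other genes. Member genes were adjusted over all tested genes and also over the list alone. The text takes its genes from the 8 largest rises and the 8 largest falls with an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between groups, from the 4 members of each list with the lowest p, and from a fixed set of cell cycle, arterial, venous and signalling genes. A result that the rule would name is not reported. Genes on the Y chromosome and genes of X inactivation were left out. Any gene outside the rule is said to be chosen after its values were seen. The venous minus arterial score is the difference of mean log2 CPM (prior count 2) between the lists, compared by an exact permutation test. Another 6 lists, of G1/S onset, S phase, lysosomal, melanocyte, macrophage and matrix genes, were written after the data had been seen.

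Alternatives were DESeq2 size factors, total count and upper-quartile scaling, the Wald test of DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (1 CPM in a whole group and a mean count of 50), a test against a 1.5-fold change, the replicate number as a block, and each library left out in turn. Thinning every library to the smallest total, a correction for GC content and gene length, and leaving out cell cycle genes were chosen after seeing the data. The procedure was tested on simulated data made from the means of these libraries, with 12776 genes of which 200 were changed. It recovered 46% of genes changed 1.2-fold, 72% at 1.5-fold, 100% at 2-fold and 100% at 4-fold (50 genes each), and 6 of 12576 unchanged genes were called, 3.64% of the calls. In the real data 21.8% of the genes differed and fold changes rose with GC content. The simulation held neither, so its shares may not hold for the real data. The list test found the 1 raised list of 21 simulated lists and 0 others, with genes drawn independently, so it does not measure false list calls among correlated genes.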

Results

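RNA-seq profiles were collected from human umbilical vein endothelial cells (HUVEC, primary cells from the vein of the umbilical cord) that carried the FUCCI reporter. FUCCI marks cell cycle position with fluorescent proteins fused to parts of CDT1 and GMNN, so that living cells can be sorted by phase. The cells were sorted by flow cytometry into early G1 (3 libraries) and late G1 (3 libraries). Total counts were 18448531, 17575562 and 21752999 in the early G1 libraries and 16021700, 19020298 and 21271586 in the late G1 libraries. Of 26475 gene symbols in the table, 18107 had at least 1 count and 12776 had enough counts to be tested. Replicate libraries of one group differed by more than sampling noise, with a chi-square per gene between 1.66 and 3.56, against 9.33 to 13.7 for libraries of different groups, so each library was counted as a separate sample. The labels do not say whether replicates came from separate cultures or donors, and p-values then measure only the spread between these libraries, which may be technical.

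The comparison of late with early G1 addressed how the endothelial transcriptome, and in particular its arterial and venous genes, differs between these parts of the cell cycle. The gene with the largest rise was GNG7, a G protein gamma subunit, at 0.654 ± 0.291 CPM (library-scaled counts; SD, n = 3) in early G1 and 13.3 ± 1.51 CPM in late G1. Its log2 fold change was 4.30 (SE 0.19; edgeR quasi-likelihood test, adjusted p = 1.6e-17), a 19.7-fold difference. NSG1, a neuronal vesicle protein, rose by 3.60 (SE 0.25) and NLRP2, an inflammasome family protein, by 2.59 (SE 0.27). These 3 rises start from few counts in the early G1 libraries: 7, 11 and 21 for GNG7, 6, 8 and 14 for NSG1, and 10, 8 and 16 for NLRP2. SCUBE1 (log2 fold change 2.15), the planar cell polarity cadherin CELSR1 (2.14), the transcription factor MITF (2.04), the lipoprotein receptor VLDLR (1.99) and the non-coding transcript LINC00520 (1.86) also rose. MITF stood at 6.36 ± 0.754 CPM in early G1 and 26.1 ± 1.8 CPM in late G1 (n = 3).

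The largest fall was that of NUP210, a nuclear pore membrane protein, which dropped by 3.68 (SE 0.32) on the log2 scale, from 4.66 ± 0.724 to 0.342 ± 0.305 CPM (n = 3). Its late G1 libraries held only 5, 1 and 14 counts. The ubiquitin-conjugating enzyme of mitotic exit UBE2C fell by 2.59 (SE 0.08), the mitotic kinase CDK1 fell by 2.57 (SE 0.07) and topoisomerase TOP2A fell by 2.42 (SE 0.05). TOP2A stood at 238.7 ± 6.70 CPM in early G1 and 44.4 ± 3.06 CPM in late G1. RNF144A fell by 2.17, the transcription factor EBF3 fell by 2.10, the kinesin KIF18B fell by 1.82 and the centromere chaperone HJURP was 4.01-fold lower. These 16 genes had the largest changes among genes past the threshold with a mean of at least 2 CPM and no overlap between the groups.

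**Figure D1:**
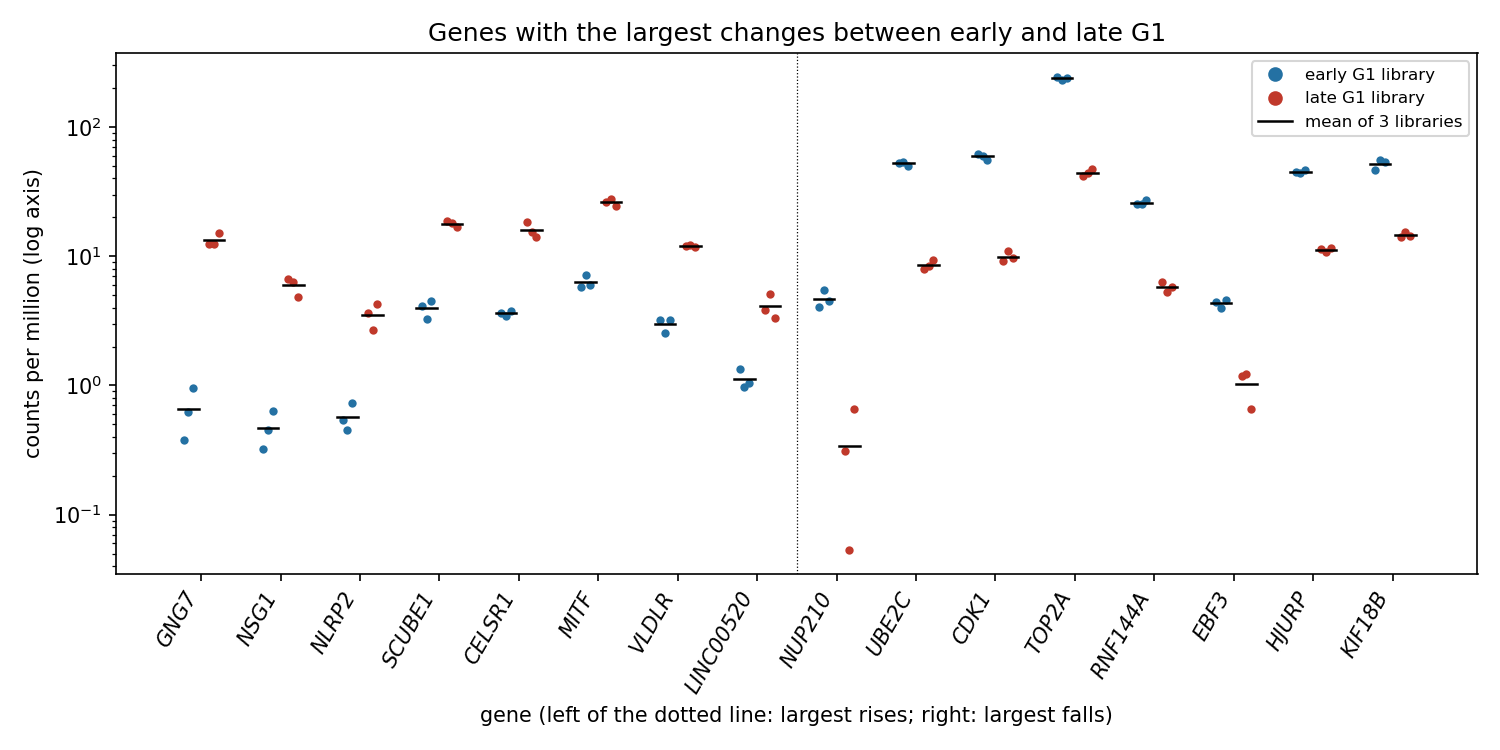
CPM (log axis) of the 8 genes with the largest rises and the 8 with the largest falls, with a point per library (3 early G1, 3 late G1) and a bar at each group mean. The values of the groups do not overlap for any of these genes, and NUP210 in late G1 lies near the floor of detection, at 0.342 ± 0.305 CPM (SD). GNG7, NSG1 and NLRP2 are also low in early G1, with means of 0.654, 0.472 and 0.575 CPM.

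In GRCh37 (hg19) coordinates, GNG7 spans 2511217 to 2702692 on chromosome 19 (minus strand) and NSG1 spans 4349867 to 4420785 on chromosome 4 (plus strand). MITF spans 69788607 to 70017487 on chromosome 3 (plus strand), NUP210 spans 13357735 to 13461822 on chromosome 3 (minus strand) and CDK1 spans 62538089 to 62554610 on chromosome 10 (plus strand). All are annotated as protein-coding, and the counts are per gene, so they do not separate exons or isoforms. GNG7, NSG1, NLRP2, SCUBE1, MITF, VLDLR, RNF144A and EBF3 overlap annotated genes on the opposite strand, and without a stated strand setting their reads could not be told apart, so their values are uncertain to that extent.

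Over all tested genes, 2787 (21.8%) differed between late and early G1 in edgeR's quasi-likelihood test at an adjusted p under 0.05, 1393 higher and 1394 lower in late G1. Most of these differences were small, with a median absolute log2 fold change of 0.26 among the differing genes. A difference of at least 2-fold was seen for 173 genes, 62 higher and 111 lower in late G1. The early and late values did not overlap for 4511 tested genes (35.3%), against 10% by chance. With upper-quartile scaling 59.9% of the differing genes were higher in late G1, against 49.98% with TMM scaling and 43.4% with total count scaling, so the even split rests on the scaling. The fold changes also rose with GC content across genes (Spearman's rho 0.21 over 12510 genes, which are not independent replicates). Of 30 gene lists 19 passed the camera test, and 9 of these no longer passed with an estimated correlation between genes. In the 9 splits of the libraries that mixed the groups, 6 to 13 lists passed camera with the preset correlation. Each of these splits kept part of the group difference, so these counts are not a rate of false list calls. A test against a 1.5-fold change gave 160 genes, 36 higher and 124 lower.

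Cell cycle genes were lower in late G1, most of all those of mitosis. All 45 genes of the G2/M and mitosis list fell, with a median log2 fold change of -1.07 (camera, adjusted p = 8.63e-93), and the proliferation marker MKI67 fell by 1.24 (SE 0.04), from 395.4 ± 5.90 to 168 ± 10.54 CPM (n = 3). Of 27 origin licensing and firing genes 26 fell and 1 did not pass (median -0.41, adjusted p = 2.07e-24). Among them the helicase activators CDC45 and GINS1 fell by 0.92 (SE 0.07) and 0.86 (SE 0.07), the helicase subunit MCM7 by 0.47 (SE 0.04) and TICRR by 1.02 (SE 0.09). Of 23 polymerase and fork genes 20 fell and 3 did not pass (median -0.40, adjusted p = 6.7e-15), with the sliding clamp PCNA at -0.44 (SE 0.05) and POLA2 at -0.54 (SE 0.06). Of 30 G1/S cyclin and E2F target genes 21 fell and 9 did not pass (median -0.43, adjusted p = 5.13e-19), among them the ribonucleotide reductase subunits RRM2 (-0.84, SE 0.04) and RRM1 (-0.57, SE 0.04). No member of these 4 lists rose. Adjusted over the list alone, 45, 26, 22 and 22 genes fell in the mitosis, licensing, fork and G1/S lists.

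The E-type cyclins did not pass the test. CCNE1, the cyclin E that drives entry into S phase, had a log2 fold change of 0.17 (SE 0.10, edgeR adjusted p = 0.25), and CCNE2 had one of -0.05 (SE 0.08, adjusted p = 0.74). Both source genes of the reporter fell, CDT1 by 0.44 (SE 0.06) and GMNN by 0.50 (SE 0.07). CDT1 lies on chromosome 16 from 88870197 to 88875666 and GMNN on chromosome 6 from 24775159 to 24786327, both on the plus strand. Whether reads of the reporter were counted with these genes is not given in the sources used here. Of 20 replication-dependent histone genes only 6 had enough counts to be tested, of which 1 fell, 5 did not pass and 0 passed when adjusted over the list alone (median -0.27, adjusted p = 0.399). The median of these replication-dependent histones was 0.02 without early G1 replicate 2 and -0.42 without early G1 replicate 3. Without the low-count filter the list passed, with a median of -0.69 (adjusted p = 0.0209, in a range of 0.0209 to 0.861 over the settings tried). Of the 14 untested histone genes 12 had fewer counts in late G1 and 2 had more, with 230 counts in all in early G1 and 135 in late G1 and at most 17 per gene and library. Near-identical copies make these genes uncertain.

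**Figure D2:**
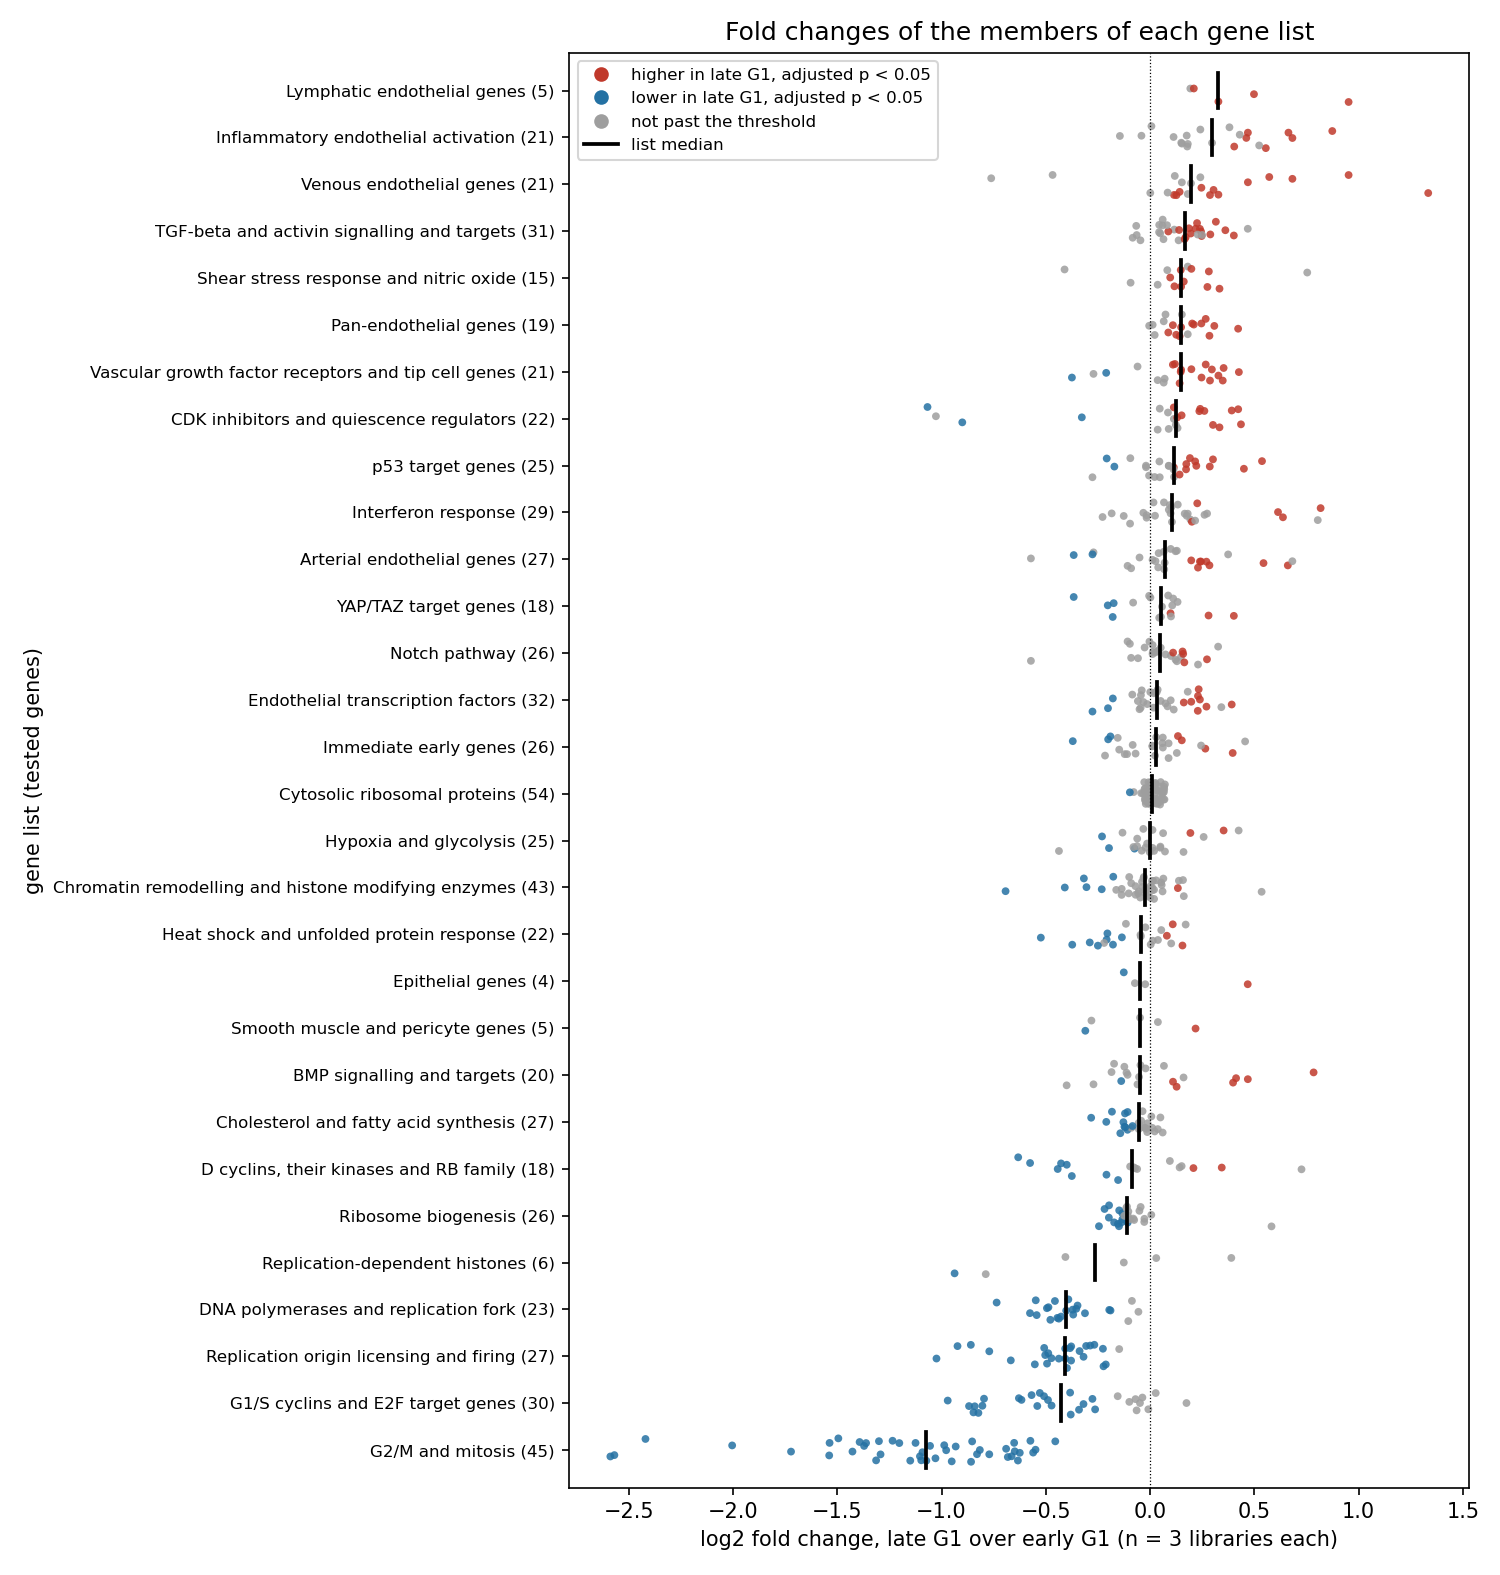
Log2 fold change (late over early G1, n = 3 libraries each) of each tested member of the 30 gene lists with at least 3 tested genes, with the number of tested genes in brackets and a bar at the list median. The mitosis list has the lowest median (-1.07), and all 45 of its genes lie below 0.

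Regulators of G1 moved both ways. The D-type cyclin CCND1 rose by 0.21 (SE 0.03), from 909.3 ± 10.7 to 1050 ± 2.13 CPM (n = 3), while the kinase CDK2 fell by 0.44 (SE 0.06), MYBL2 by 0.58 (SE 0.04) and LIN9, a subunit of the complex that MYBL2 joins, by 0.63 (SE 0.11). In the list of D cyclins, their kinases and the RB family, 2 of 18 genes rose, 8 fell and 8 did not pass, against 5 and 8 adjusted over the list alone (median -0.09, camera adjusted p = 0.0232). With an estimated correlation the adjusted p of this list was 0.106. Among CDK inhibitors, CDKN2A rose by 0.44 (SE 0.06), CDKN2B by 0.42 (SE 0.08) and CDKN1A by 0.11 (SE 0.03), while CDKN2C fell by 1.07 (SE 0.09) and CDKN1B by 0.33 (SE 0.07). CDKN2A and CDKN2B overlap the antisense transcript CDKN2B-AS1, whose reads could not be told apart from theirs. CDKN1A did not pass without the late G1 replicate 3 (adjusted p = 0.063, the highest of a range from 0.0037 over the settings tried). Of the 22 tested genes in the list of CDK inhibitors and quiescence regulators, 11 rose, 3 fell and 8 did not pass, against 13 and 4 adjusted over the list alone. The list was higher in late G1 (median 0.13, mean 0.01, adjusted p = 0.00747), with an adjusted p of 0.148 with an estimated correlation. Targets of p53 were also higher, with 11 rises, 2 falls and 12 not past among 25 genes and 12 and 2 adjusted over the list alone (median 0.11, adjusted p = 0.00249). For this list the estimated correlation gave an adjusted p = 0.0873, and its members TP53INP1 (0.45, SE 0.05) and the death receptor TNFRSF10B (0.22, SE 0.03) rose.

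Immediate early genes, the first to respond to growth factors, did not differ as a group, with 4 rises, 3 falls and 19 not past among 26 tested genes and 4 and 3 adjusted over the list alone (median 0.03, camera adjusted p = 0.623). FOSL1 fell by 0.37 (SE 0.04) and JUNB rose by 0.40 (SE 0.08). MYC rose by 0.13 (SE 0.04, edgeR adjusted p = 0.012), a call that was lost without early G1 replicate 1 (adjusted p = 0.054) and without late G1 replicate 3 (adjusted p = 0.0998), in a range from 0.0034 over the settings tried.

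Venous endothelial genes were higher in late G1. The hyaluronan receptor LYVE1 rose by 0.95 (SE 0.07), from 19.9 ± 1.498 to 38.5 ± 1.53 CPM (n = 3), the cyclooxygenase PTGS1 by 0.57 (SE 0.05), the ephrin receptor EPHB4 by 0.30 (SE 0.04), the semaphorin receptor NRP2 by 0.29 (SE 0.03) and FLT4 by 0.33 (SE 0.07). NR2F2, the transcription factor of venous identity, had a log2 fold change of 0.00 (SE 0.03, edgeR adjusted p = 0.99) at 516.2 ± 19.7 CPM in early and 516.8 ± 15.8 CPM in late G1. Of 21 tested venous genes 12 rose, 0 fell and 9 did not pass, against 13 and 1 adjusted over the list alone. Their median was 0.20 (camera adjusted p = 1.84e-07, and 0.0232 with an estimated correlation). The pan-endothelial list also rose, with a median of 0.15, and whether venous genes rose beyond it was not tested. VWF belongs to both lists, SELP also to the inflammatory list, and NRP2 and FLT4 also to the growth factor receptor list. EPHB4 lies on chromosome 7 from 100400187 to 100425145 (minus strand).

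Arterial genes moved in both directions. C10orf10 (now DEPP1) rose by 0.66 (SE 0.06), the hypoxia-inducible factor EPAS1 by 0.23 (SE 0.03), the receptor ACVRL1 by 0.24 (SE 0.03), the junction protein CLDN5 by 0.28 (SE 0.04) and SOX17 by 0.20 (SE 0.05), while GATA2 fell by 0.28 (SE 0.04). The arterial genes EFNB2 (0.04, SE 0.05), DLL4 (0.12, SE 0.09), HEY1 (-0.11, SE 0.11), NOTCH1 (0.04, SE 0.04) and CXCR4 (0.07, SE 0.11) did not pass the test, with adjusted p between 0.40 and 0.72. The gap junction genes GJA4 and GJA5 had at most 10 and 3 counts in a library, with 18 and 3 counts in all in early G1 and 17 and 5 in late G1, and a small difference in them was not detectable at this depth. Of 27 tested arterial genes 8 rose, 2 fell and 17 did not pass, against 9 and 2 adjusted over the list alone. Their median was 0.07 (camera adjusted p = 0.00747), and the adjusted p was 0.216 with an estimated correlation. The mean log2 CPM of the venous list minus that of the arterial list was -0.26 ± 0.04 (SD, n = 3) in early G1 and -0.11 ± 0.05 in late G1. The difference of 0.16 gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow.

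**Figure D3:**
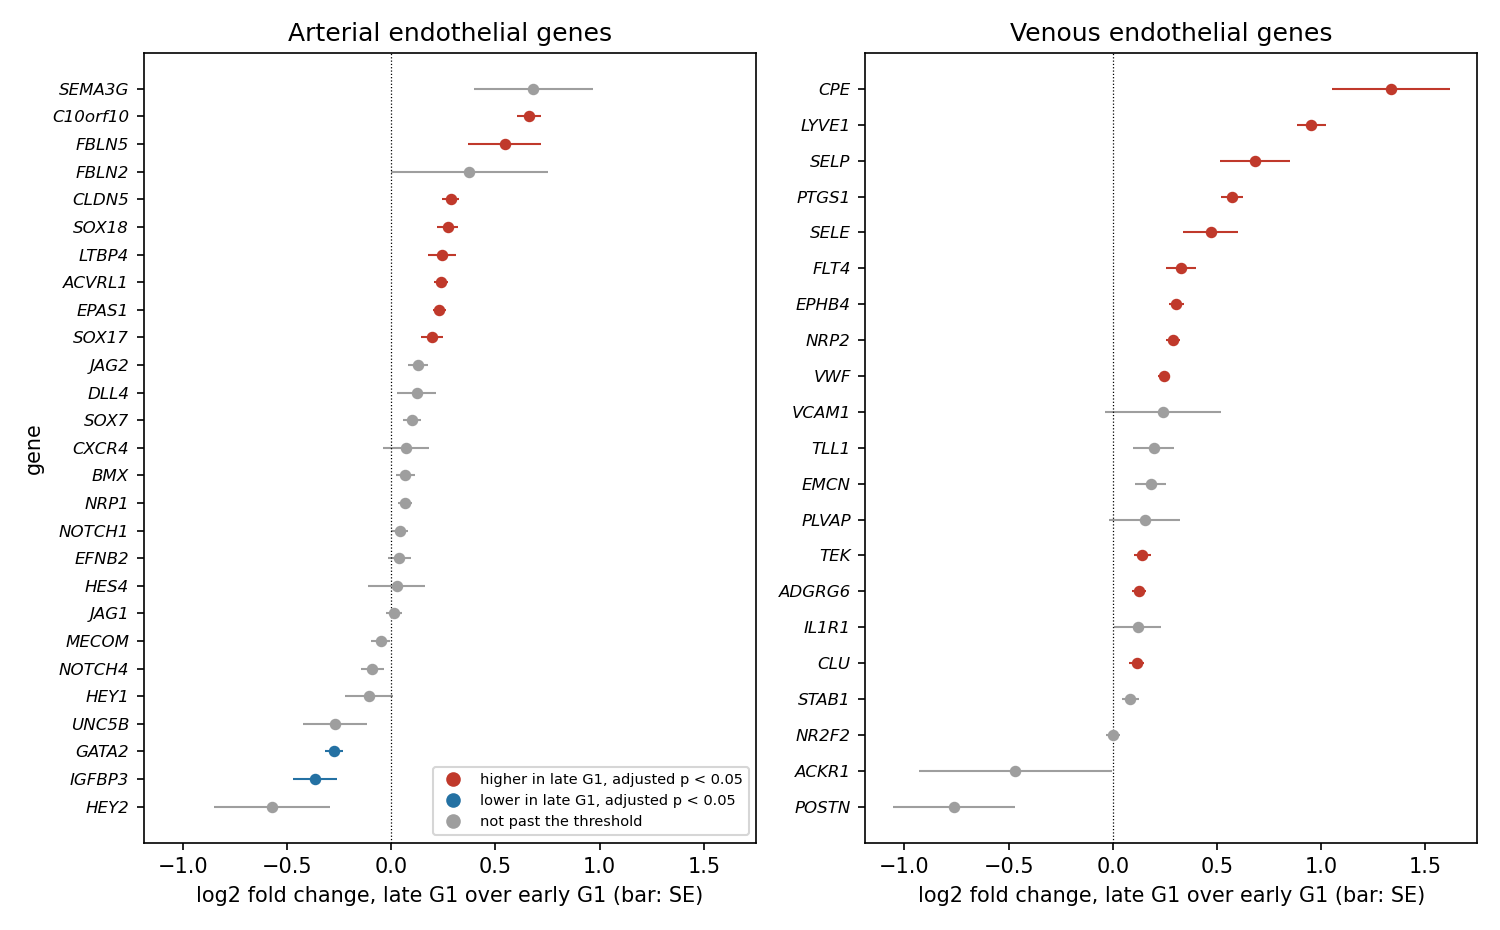
Log2 fold change (late over early G1, n = 3 libraries each; bar, SE) of each tested gene of the arterial and venous lists, coloured by whether it was past an adjusted p of 0.05. Of the venous genes 12 were higher and 0 lower in late G1, and of the arterial genes 8 were higher and 2 lower.

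Of 26 tested Notch pathway genes 5 rose, 0 fell and 21 did not pass, with 6 and 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.101). The protease ADAM17 rose by 0.16 (SE 0.04) and the Notch target HES1 by 0.27 (SE 0.08). HES1 did not pass without early G1 replicate 2 (adjusted p = 0.098), late G1 replicate 1 (0.073) or late G1 replicate 3 (0.051), and its adjusted p ranged from 0.0078 to 0.098 over the settings tried. Genes of TGF-beta and activin signalling and their targets were higher, with 15 of 31 rising, 0 falling and 16 not past, against 17 and 0 adjusted over the list alone. The median was 0.17 (adjusted p = 1.39e-08, and 0.0273 with an estimated correlation). The type IV collagens COL4A1 and COL4A2 rose by 0.36 (SE 0.03) and 0.25 (SE 0.03), the latent TGF-beta binding protein LTBP2 by 0.29 (SE 0.03) and the endothelial type I receptor ACVRL1 by 0.24 (SE 0.03), while the other type I receptor TGFBR1 stood at -0.08 (SE 0.08, edgeR adjusted p = 0.54).

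The BMP list held both directions. The ligands BMP4, BMP2 and BMP6 rose by 0.40 (SE 0.04), 0.41 (SE 0.08) and 0.13 (SE 0.04), the inhibitor SMAD6 by 0.78 (SE 0.12) and the receptor BMPR2 by 0.11 (SE 0.03). BMPR2 was lost without early G1 replicate 3 (adjusted p = 0.108) or late G1 replicate 2 (0.110), in a range from 1.86e-04 over the settings tried. The target gene ID1 had a log2 fold change of -0.12 (SE 0.05, adjusted p = 0.10), which passed after a correction for GC content and gene length (adjusted p = 0.0255, in a range of 0.0255 to 0.357 over the settings tried). Of 20 tested BMP genes 6 rose, 1 fell and 13 did not pass, also when adjusted over the list alone. The median of -0.05 and the mean of 0.04 differed in sign, and the camera test, which pointed higher, gave an adjusted p = 0.324.

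Among 32 endothelial transcription factors 8 rose, 3 fell and 21 did not pass, with the same counts adjusted over the list alone (median 0.03, camera adjusted p = 0.0947). TCF4 rose by 0.23 (SE 0.04) and SOX18 by 0.27 (SE 0.05). Of 43 chromatin remodelling and histone modifying enzymes 1 rose, 6 fell and 36 did not pass, against 0 and 6 adjusted over the list alone (median -0.02, adjusted p = 0.13). The DNA methyltransferases DNMT1 and DNMT3B fell by 0.30 (SE 0.04) and 0.69 (SE 0.12), and the Polycomb subunit EED by 0.41 (SE 0.08). This list passed without early G1 replicate 1 (adjusted p = 0.0318), without late G1 replicate 2 (0.0211) and after the correction for GC content and gene length (0.0415), in a range of 0.0211 to 0.47 over the settings tried.

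Pan-endothelial genes were slightly higher in late G1. PECAM1 rose by 0.31 (SE 0.03), from 1479 ± 19.5 to 1832 ± 11.9 CPM (n = 3), the VEGF receptor KDR by 0.27 (SE 0.04), VWF by 0.25 (SE 0.03) and the cadherin CDH5 by 0.20 (SE 0.03). Of 19 genes 12 rose, 0 fell and 7 did not pass, against 13 and 0 adjusted over the list alone. The median was 0.15 (camera adjusted p = 3.93e-09, and 0.0273 with an estimated correlation) and 0.10 after the correction for GC content and gene length. Among 21 vascular growth factor receptor and tip cell genes 14 rose, 2 fell and 5 did not pass, also adjusted over the list alone (median 0.15, adjusted p = 1.8e-06, and 0.0562 with an estimated correlation). The placental growth factor PGF rose by 0.43 (SE 0.04), PLXND1 by 0.35 (SE 0.03) and PDGFB by 0.30 (SE 0.04). Lymphatic endothelial genes were higher, with 4 rises, 0 falls and 1 not past among 5 tested, also adjusted over the list alone (median 0.33, adjusted p = 5.75e-05, and 0.0985 with an estimated correlation). They include LYVE1 and FLT4, which the venous list also holds, and RELN, which rose by 0.50 (SE 0.11).

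Genes of endothelial activation were higher as well. The adhesion molecule ICAM1 rose by 0.56 (SE 0.06), the chemokine CCL2 by 0.46 (SE 0.07) and P-selectin, SELP, by 0.68 (SE 0.17). Of 21 tested inflammatory genes 7 rose, 0 fell and 14 did not pass, against 10 and 0 adjusted over the list alone (median 0.30, camera adjusted p = 0.000413, and 0.0436 with an estimated correlation). Of 15 tested shear stress and nitric oxide genes 9 rose, 0 fell and 6 did not pass, against 10 and 0 adjusted over the list alone (median 0.15, adjusted p = 0.00014, and 0.0436 with an estimated correlation), with endothelin EDN1 at 0.28 (SE 0.03) and the haem oxygenase HMOX1 at 0.28 (SE 0.05). Of 29 tested interferon response genes 5 rose, 0 fell and 24 did not pass, with 5 and 0 adjusted over the list alone (median 0.11, adjusted p = 0.00747, and 0.0733 with an estimated correlation). IFI27 rose by 0.64 (SE 0.05) and OAS2 by 0.82 (SE 0.18).

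Ribosome biogenesis genes were lower in late G1, with 12 of 26 falling, 0 rising and 14 not past, against 15 falls and 1 rise adjusted over the list alone. The median was -0.11 (camera adjusted p = 1.55e-05, and 0.0273 with an estimated correlation). The nucleolar proteins NCL and FBL fell by 0.15 (SE 0.03) and 0.17 (SE 0.04). Cholesterol and fatty acid synthesis genes were also lower, with 11 falls, 0 rises and 16 not past among 27, also adjusted over the list alone (median -0.05, adjusted p = 0.00747, and 0.0733 with an estimated correlation). Their member EBP fell by 0.21 (SE 0.05). Of 22 heat shock and unfolded protein genes 3 rose, 8 fell and 11 did not pass, against 4 and 9 adjusted over the list alone (median -0.05, adjusted p = 0.0382). That call was lost without early G1 replicate 2 (0.081), late G1 replicate 1 (0.0547) or late G1 replicate 3 (0.0597), with upper-quartile scaling (0.0631) and with the stricter low-count filter (0.0601), and the adjusted p was 0.272 with an estimated correlation and as low as 0.00786 over the settings tried. The chaperones HSPA8 and HSP90AA1 fell by 0.21 (SE 0.03) and 0.20 (SE 0.03).

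Hypoxia and glycolysis genes did not differ as a group, with 2 rises, 3 falls and 20 not past among 25 tested, also adjusted over the list alone (camera adjusted p = 0.701). Their median of -0.0017 and the camera direction were lower, and the mean of 0.01 was higher. LDHA fell by 0.20 (SE 0.03) and ADM rose by 0.35 (SE 0.06). Of 18 tested YAP/TAZ target genes 3 rose, 4 fell and 11 did not pass, against 8 and 4 adjusted over the list alone (median 0.05, adjusted p = 0.264, and 0.0214 with fry), with AXL at -0.18 (SE 0.03). Of 54 cytosolic ribosomal protein genes 0 rose, 1 fell and 53 did not pass, against 0 and 0 adjusted over the list alone (median 0.01, adjusted p = 0.252). The adjusted p of that list was 0.00318 without early G1 replicate 1 and 0.0333 with upper-quartile scaling, in a range of 0.00318 to 0.82 over the settings tried. Of 13 mitochondrially encoded genes 0 were found in the table by symbol, so their share is not analysed here.

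Genes used as markers of other cell types ranged from undetected to abundant. RGS5 of the smooth muscle and pericyte list stood at 1335 ± 43.5 CPM in early G1 and 1291 ± 23.6 CPM in late G1 (n = 3), SMTN of the same list at 387.8 ± 20.4 and 312.7 ± 9.37 CPM, and the keratin KRT18 at 257.1 ± 8.77 and 235.5 ± 6.87 CPM. KRT18 fell by 0.13 (SE 0.04), a call lost without late G1 replicate 2 (edgeR adjusted p = 0.078, in a range from 0.000499 over the settings tried). Of 14 smooth muscle and pericyte genes 5 were tested, of which 1 rose, 1 fell and 3 did not pass (adjusted p = 0.351, and 0.0065 with fry), the same counts as adjusted over the list alone. The fall was that of SMTN (-0.31, SE 0.04) and the rise that of TAGLN (0.22, SE 0.08, edgeR adjusted p = 0.0497). The call of TAGLN was lost under 12 of the other settings, among them without early G1 replicate 1 (0.140), 2 (0.113) or 3 (0.057) and without late G1 replicate 1 (0.0577) or 3 (0.249), in a range from 0.0296. Only 1 of 14 fibroblast genes could be tested, COL1A2, which rose by 0.51 (SE 0.11) from 6.96 ± 0.616 to 9.94 ± 0.466 CPM (n = 3). Only 1 of 15 leukocyte genes could be tested, the lysosomal protein CD68 at 0.19 (SE 0.07, edgeR adjusted p = 0.043), whose call was lost without early G1 replicate 1 (0.144) or 2 (0.115) and without late G1 replicate 1 (0.0682), 2 (0.135) or 3 (0.069). It was also lost with the DESeq2 Wald test (0.110), total count scaling (0.065), no low-count filter (0.0536) and thinned libraries (0.0591). With the replicate block the edgeR adjusted p of CD68 was 0.0597. Over the settings tried the adjusted p of CD68 ranged from 0.0237 to 0.144. Of 11 epithelial genes 4 were tested, with 1 rise, 1 fall and 2 not past, also adjusted over the list alone (camera adjusted p = 0.774), where the median of -0.05 and the mean of 0.06 differed in sign. The rise was that of CLDN7 (0.47, SE 0.11). None of 9 erythroid genes had enough counts to be tested, and the highest count among them was 2. PTPRC, the pan-leukocyte gene, chosen after its values were seen, had 0 counts in all 6 libraries, where 3 counts amount to 0.138 to 0.187 CPM as the upper limit from counting error alone.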

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

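The thinning, the correction for GC content and length and the setting without cell cycle genes were chosen only after the result was seen. The count of differing genes was 2124 to 3159 over the settings other than leaving out a library or testing against a 1.5-fold change, and 2084 to 2496 with a library left out. Testing against a 1.5-fold change gave 160 genes, 36 higher and 124 lower, since that test asks for a larger change. The correction for GC content and length gave 3159 genes, 2479 of them shared with the 2787 of the uncorrected test. The correlation of fold change with GC content over genes was 0.21 before and -0.0065 after it.

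Of 1946 comparisons of the 116 named genes with another setting, 1904 kept direction and side of the threshold, 31 lost the call (TAGLN, CD68, HES1, MYC, BMPR2, CDKN1A and KRT18), 1 gained it (ID1) and 10 changed sign. The sign changes are those of genes near 0 that passed under no setting. NR2F2 stood at -0.0136 with total count scaling, -4e-04 with limma-voom, -0.0019 after thinning, -0.0212 after the GC content and length correction and -0.0293 to 0.0243 with a library left out. NOTCH1 stood at -0.0495, CCNE2 at 0.0031 and RGS5 at 0.0122 after that correction, and NOTCH1 at -0.0205 to 0.0808 with a library left out. The cause was not tested.

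Of 503 comparisons of the 30 gene lists, 476 kept direction and side, 14 lost the call, 11 gained it and 2 changed direction. With an estimated correlation the D cyclin, CDK inhibitor and arterial lists had adjusted p of 0.106, 0.148 and 0.216. That setting estimates a correlation for each list, and 9 lists lost their call under it. For the D cyclin (-0.00871), interferon (-0.0317) and cholesterol lists (-0.0205) the estimate lay below the preset 0.01, so correlated genes do not account for their loss. For the others it lay above, from 0.0206 to 0.36. This setting also uses fewer degrees of freedom, which raises p by itself. The licensing list, with an estimate of -0.0177, went from a camera p of 1.38e-25 to 0.000299. How much of each loss is due to correlation was therefore not separated. With fry, which does not compare a list with other genes, the Notch (0.0211), BMP (0.00547) endothelial transcription factor (0.0373), YAP/TAZ (0.0214) and smooth muscle lists (0.0065) passed. The histone list passed without the low-count filter (0.0209), which brings in genes of few counts. The direction of the immediate early list changed after the GC content and length correction (adjusted p = 0.961) and that of the epithelial list without late G1 replicate 2 (0.624 to 0.875 with a library left out), and the cause was not tested. The DESeq2 Wald test, limma-voom and 1.5-fold settings give no list value of their own.

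With the replicate block 2477 genes differed, 2467 of them shared with the test without it. No list and 2 named genes, CD68 and TAGLN, lost a call. The deviations of libraries with the same number correlated at -0.137, -0.134 and 0.081, so the numbers were not taken to pair the libraries. The highest values joined different numbers, early G1 replicate 1 with late G1 replicate 2 (0.186) and early G1 replicate 2 with late G1 replicate 1 (0.139). Deviations from a mean of 3 libraries make this a weak check of pairing. Few counts limit what can be said of genes such as GJA4, GJA5, the histone genes and NUP210 in late G1. Why the histone genes had so few counts was not tested, so depth cannot be named as the reason.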

Other observations

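Many lysosomal genes were higher in late G1. The phosphotransferase subunit GNPTG rose by 0.59 (SE 0.04), the saposin precursor PSAP by 0.38 (SE 0.03), progranulin, GRN, by 0.40 (SE 0.03) and cathepsin CTSB by 0.34 (SE 0.03; edgeR adjusted p = 7.5e-11). Of 52 tested lysosomal genes 31 rose, 1 fell and 20 did not pass, against 32 and 1 adjusted over the list alone, with a median log2 fold change of 0.18. The lysosomal and matrix lists and these genes, as well as GPNMB, were chosen after their values were seen. Neither list was run with the correction for GC content and gene length, although fold changes rose with GC content across genes.

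Many basement membrane and matrix genes were higher in late G1 too. The heparan sulfatase SULF2 rose by 0.70 (SE 0.04), netrin NTN4 by 0.50 (SE 0.03), the gelatinase MMP2 by 0.37 (SE 0.03) and the collagen COL5A1 by 0.34 (SE 0.03; edgeR adjusted p = 1.2e-09). Of 29 tested matrix genes 25 rose, 0 fell and 4 did not pass, against 26 and 0 adjusted over the list alone, with a median log2 fold change of 0.21. Since the list was written after its genes' values were seen, no set test is given for it. Of 9 melanocyte genes 1 had enough counts to be tested and did not pass, and of 12 macrophage genes 0 had enough. COL4A1 and COL4A2 belong both to the matrix list and to the TGF-beta list.

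The tests of onset, S phase, melanocyte, macrophage, lysosomal and non-endothelial genes below were chosen only after the result was seen, as were the thinning, GC content and cell cycle gene settings. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2787 genes, 1393 higher and 1394 lower, and 19 lists, against 0 genes and 6 to 13 lists in the 9 other splits, so 1 split in each case gave as many as the real one, itself. The other splits each kept part of the group difference and held the rest inside their sides, where it widens the spread. Their counts therefore give no rate of false calls.

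Transcripts of mitosis, licensing and replication were lower in late G1. Depth and GC content are argued against, since 45 of 45 mitosis genes were lower after thinning and their median was -1.071 after the correction for GC content and length. G1/S onset genes (median -0.26) stood 0.31 above S phase genes (median -0.57), which stood 0.503 above mitosis genes (median -1.07), but the onset and S phase lists were written after their genes' values were seen, so these differences decide nothing. Lower E2F-driven transcription in late G1 therefore stays open, as do transcripts of the preceding phases in the early G1 sort, whether inherited through mitosis or from S, G2 or M cells inside the early gate. The gates are not given in the sources used here.

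MITF rose 4.12-fold, and GPNMB, a melanosomal and lysosomal glycoprotein, rose by 3.51 (SE 0.32), from 16 counts over the early G1 libraries to 179 over the late ones. Melanocytes in the late sort are argued against, since PMEL, MLANA, TYR and DCT together gained 5 counts (±15.1 at 2 times the counting error) where GPNMB gained 163, and macrophages likewise, with a gain of 5 counts (±12.5) over 12 macrophage genes. The bound first set, a late count under 17.9, was missed by both (31 and 22), but the early libraries already held 26 and 17 such counts, so that bound did not measure a gain. The bound on the gain was set after these counts were seen, so it is no prediction, and only the size of the gains speaks against these cells. A set test of the lysosomal list (camera with an estimated correlation, p = 0.00278) is void, since the list was written after its genes' values were seen, and a difference between early and late G1 cells themselves stays open, as untested.

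Pan-endothelial genes were higher in late G1, with a median of 0.149. The median was 0.148 without the genes of the cell cycle lists, so the fall of those genes did not set it through the scaling. TMM already trims genes of large change and other falling genes stayed in, so this setting decides nothing about scaling in general. The median over all tested genes was -0.0148 with total count scaling and 0.0211 with upper-quartile scaling. Fewer fibroblasts, leukocytes, erythroid or smooth muscle cells were weighed with 10 of their abundant transcripts. These made up at most 0.000184% of an early G1 library and 0.000108% of a late one. They were chosen after the result was seen and leave out RGS5 (1335 CPM in early G1) and SMTN, so they decide nothing. In the lists fixed beforehand, untested fibroblast, leukocyte and erythroid genes had at most 11, 10 and 2 counts in a library. Some of these genes fell, such as COL3A1 from 21 to 4 counts in all, and others rose, such as PDGFRA from 19 to 24. The low counts argue against a loss of those cells. The tested members COL1A2 and CD68 did not fall, but CD68 is lysosomal and many lysosomal genes rose, so it does not count here. Untested smooth muscle and pericyte genes also had at most 10 counts, with CNN1, DES, MYOCD and ACTG2 at 0 in all 6 libraries. These counts argue against a loss of smooth muscle cells too, for the genes they cover, although SMTN fell and RGS5 was abundant. Detected members of the smooth muscle and epithelial lists went both ways: SMTN fell by 0.31 and KRT18 fell by 0.13, while CLDN7 rose by 0.47 and TAGLN stood at 0.22, a call lost in 5 of 6 cases with a library left out (adjusted p up to 0.249, without late G1 replicate 3). GC content could carry part of the pattern. After the correction the median was 0.104, above the bound of 0.1 by less than the median standard error of the list's genes (0.028). The list still passed its test (camera adjusted p = 2.01e-06), and a difference between early and late G1 cells themselves stays open, as untested.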
